A study of Homo sapiens with 4 samples.

How the data were processed

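RNA was measured in SUM149 cells, an established line from a triple-negative inflammatory breast cancer, that carried the surface profile CD44 positive, CD24 negative and EpCAM positive. Per the labels, cells were treated with PBS (the vehicle) or with erythropoietin (EPO), total RNA was isolated with a Qiagen RNeasy kit, and each sample was hybridised to a human Agilent array of 2 colours, with Universal Human RNA Reference in Cy3 and cell RNA in Cy5. There were 2 PBS arrays and 2 EPO arrays, numbered replicate 1 and replicate 3 in each group. The source field of the cell channel in the labels names mouse tissue on these arrays; treatment, cell type and description all name SUM149 cells, and these were followed. The labels do not say whether the replicates were separate cultures or sorts, so the p-values below measure only the spread between these RNA samples. Treatment dose and time, slide and hybridisation batch are not in the labels.

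The deposited values are log2 ratios of the 2 channels, 1 per array feature, normalized by the authors with a method that neither the labels nor the headers state. The base of the logarithm is not stated either. The largest absolute value, 12.4, is a channel ratio of 5334 on a log2 scale and of 238232 on a natural log scale, which exceeds the highest value of a 16-bit scanner, 65535. Array medians were 0.015 and 0.027 for PBS replicates 1 and 3 and 0.013 and 0.009 for EPO replicates 1 and 3, so arrays were centred near 0, and genes were not centred across arrays. Which channel is the numerator is not stated. It was read from a pair of gene lists fixed beforehand: liver and melanocyte genes, present in the reference pool, lay below 0 and basal epithelial genes above 0, so ratios were taken as cells over reference. Only these ratios were used. Channel intensities, background and saturation were not analysed here, so whether a feature was above background is unknown, and precision is limited by the number of arrays.

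Each array had 45220 features with no missing value. The platform annotation gave 1 gene symbol to 31332 features and several to 93, and 13795 features are unnamed here. Gene IDs of 31291 features were found in the RefSeq table of the GRCh38.p14 assembly, used for names only, and 0 symbols changed. Features of a gene were averaged, giving 18334 genes, of which 7759 had more than 1 feature (at most 16). No other filter was applied. Among 238 sets of at least 8 features for 1 gene, the median SD within an array was 0.092 on the log2 scale (quartiles 0.056 to 0.29). Such features may probe different parts of a transcript.

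Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, all 4 arrays, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are EPO minus PBS on the log2 scale, with limma's standard error (SE) or 95% confidence interval. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 34 lists with at least 5 measured members, out of 37 fixed. The other lists were the 3 sorting-gate genes and the pair of lists for direction. Fry, camera on ranks and camera with an estimated correlation were run as alternatives. The last of these rests on the residual degrees of freedom, 2 for 4 arrays in 2 groups, and so has little power over 34 lists. A list's median was also set beside 10000 random lists of the same size, matched on mean ratio to the reference in 50 bins. Genes with both EPO arrays above, or both below, both PBS arrays were counted at an absolute difference of at least 1, a fold of 2, and the count was repeated for the other 2 splits of the arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

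The steps were tested on simulated data with 18334 genes, 2 arrays per group and 200 changed genes. Variances were drawn from the distribution limma fitted to these arrays, with the largest capped. Of genes changed by 1 on the log2 scale 36.9% were called, of those changed by 2, 81.3%, and of those changed by 3, 91.7%. At most 14 other genes were called in a simulation, a count that can include members of the lists shifted by 0.25. With no change, 0 genes were called in any simulation and a mean of 924 had an unadjusted p under 0.05. Lists shifted by 0.25 were called in 100% of cases, with a mean of 0.1 false list calls. The simulated genes varied independently, which real genes of a list do not. Their variances also did not depend on the mean ratio to the reference. The SD of the real EPO minus PBS differences was 0.70 for genes with a mean ratio below -4, against 0.18 from 1 to 2. The shares called may thus be too high for genes of low ratio.

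Gene lists, tests, alternatives and the rule for named genes were chosen before the data were examined. Named were the 12 largest rises and the 12 largest falls past the threshold or, where fewer passed, those with an unadjusted p under 0.01 and no overlap between groups, passing over clone-like symbols. Also named were EPO, its receptor and signalling genes and the sorting-gate genes, up to 2 members at each end of each list, and the 10 highest and 10 lowest genes against the reference. ADM, VEGFA, SLC2A1, KRT5, LCN2 and IL1B, and CD2, MS4A1, PTPRC, ITGAM and IL2RA, were named after their values were seen. Alternatives chosen beforehand were other centring and quantile normalization, single features, a filter on genes near the reference level, other variance models, array weights, a replicate block, other set tests and leaving out each array. Scaling arrays to 1 SD or 1 median absolute deviation was added after the data were seen, as were the matched random lists, a list of epidermal differentiation genes and the count of genes at an unadjusted p under 0.05.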

Results

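The series set out to ask how erythropoietin acts on tumour-initiating cells of breast cancer, as its title states. Transcripts were measured in SUM149 cells carrying the CD44 positive, CD24 negative, EpCAM positive profile used to enrich such cells. A group of 2 arrays held cells treated with PBS and a group of 2 held cells treated with EPO, the hormone that drives red cell formation. Each array gave the log2 ratio of cell RNA to a common reference RNA, which cancels when groups are compared. Across 18334 genes, Pearson's r was 0.957 between the PBS arrays, 0.954 between the EPO arrays and 0.947 to 0.951 between arrays of different groups. These are correlations across genes, which are not independent replicates. The SD of log2 ratios was 1.30 and 1.37 on PBS replicates 1 and 3 and 1.40 and 1.41 on EPO replicates 1 and 3.

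Against the reference, the cells had high ratios for basal epithelial genes and low ratios for liver and melanocyte genes. The highest ratio was that of MCF2, an oncogene that encodes a guanine nucleotide exchange factor, at 6.51 ± 0.30 (SD, n = 4 arrays, as for the levels that follow). FGFBP1, a carrier of fibroblast growth factors, had 5.66 ± 0.50, the cytokine gene IL1A 5.61 ± 0.33, the desmosomal cadherin gene DSG3 5.39 ± 0.35, the epithelial transcription factor gene EHF 5.45 ± 0.21 and the matrix protease gene MMP7 5.32 ± 0.48. COXFA4L3, TMEM154, PCDH20 and TFCP2L1 completed the 10 highest. Among the 10 lowest ratios were those of liver genes, IGFBP1 at -8.97 ± 0.22, APOH at -7.69 ± 0.79, ALB at -7.44 ± 0.22 and FABP1 at -6.63 ± 0.31. CAVIN2, A2M, RHOXF2B, MAGEA1, CD69 and COLEC12 were the others. CAVIN2 varied most among them, with an SD of 3.29. The 18 measured liver and melanocyte genes had a median ratio of -4.89, with 18 of 18 below 0, and the 14 basal epithelial genes one of 2.14, with 13 of 14 above 0. Of the sorting-gate genes, CD44 lay at 1.59 ± 0.07, EPCAM at 2.44 ± 0.19 and CD24 at -3.22 ± 0.32.

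EPO-treated cells were compared with PBS-treated cells to see which genes respond to the hormone. Among genes with an unadjusted p under 0.01 and no overlap between groups, the largest differences lay in genes of varied function. SEMG2, which encodes a seminal gel protein, had a log2 difference of 3.21 ± 0.15 (SE, 2 arrays per group, as for all differences below). S100G, a calcium-binding protein, had 2.11 ± 0.19 and CASP14, the caspase of cornifying skin, 2.0 ± 0.17. The kinase gene CDKL2 had 1.72 ± 0.07. On the other side lay TSGA13 with -2.24 ± 0.21 and the sulfotransferase gene SULT1C4 with -1.95 ± 0.09. The cancer-testis antigen gene MAGEC1 had -1.78 ± 0.08, at a low mean ratio of -6.02 to the reference. None of these passed the threshold: limma called 0 of 18334 genes, with a lowest adjusted p of 0.193, and 1530 genes had an unadjusted p under 0.05, where chance alone gives 917. Of these, 684 were higher and 846 lower in EPO arrays.

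The remaining genes among the 12 largest positive differences were LINC01580, TTTY20, RAMP2-AS1, CCDC140, CCDC178, RNF213-AS1, LINC00641 and COL26A1, from 2.27 for LINC01580 to 1.52 for COL26A1. With 1 feature per gene COL26A1 had a difference of 0 and RAMP2-AS1, at 1.94, had 0.79. Several of these are noncoding transcripts. All but COL26A1 and RAMP2-AS1 of the 12 largest positive differences came from 1 feature each. The check with 1 feature per gene does not reach them. The remaining largest negative differences, from -2.09 for KCNMB2-AS1 to -1.71 for SPATA8, were those of EVC2, a ciliary gene of hedgehog signalling, OR2B6, an olfactory receptor, ZNF542P, GPR174, PPP1R17, PNOC and F2RL2. ZNF542P, F2RL2 and KCNMB2-AS1 had low mean ratios to the reference, -3.98, -3.44 and -3.42. Both EPO arrays lay on the same side of both PBS arrays for each of the largest differences, by the rule that chose them. By size, 291 genes were apart in this way by at least 1 on the log2 scale, 81 higher and 210 lower in EPO arrays. The same count was 163 (78 and 85) when PBS replicate 1 and EPO replicate 3 were set against the other arrays, and 159 (75 and 84) when replicates 1 were set against replicates 3. With no minimum size 7037 genes were apart, where chance gives 33.3% of 18334 genes. A gene whose arrays all differ is apart in exactly 1 of the splits, so a surplus in 1 lowers the counts of the others. Leaving out 1 array at a time gave 439 to 508 genes apart by at least 1.

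Hypoxia target genes lay higher with EPO as a list, by less than the PBS arrays differed between themselves. The 29 measured genes of the hypoxia-inducible factor list had a median difference of 0.22 (camera adjusted p = 8.85e-07, and 0.866 with an estimated correlation), against a median gap of 0.40 between PBS replicates 1 and 3. All 29 differences were positive, and in 16 of 29 genes both EPO arrays lay above both PBS arrays. NDRG1, a stress-responsive gene, had 0.72 ± 0.31, ANGPTL4, a regulator of lipid uptake, 0.71 ± 0.16, ADM, the vasodilator adrenomedullin, 0.61 ± 0.38, VEGFA 0.31 ± 0.13 and the glucose transporter gene SLC2A1 0.32 ± 0.10. PLOD1, at 0.10 ± 0.08, and KDM3A, at 0.01 ± 0.11, were the smallest. No member passed the gene test over all genes, 0 passed adjusted over the list alone, and 2 had an unadjusted p under 0.05. Fry gave the list an adjusted p of 0.597. PBS replicate 3 was the lowest of the 4 arrays for 28 of 29 genes, and ADM ran from 0.63 in PBS replicate 1 and -0.39 in PBS replicate 3 to 0.69 and 0.77 in the EPO arrays. Without PBS replicate 3 the list's median was 0.10 (adjusted p = 0.036), with 22 of 29 genes above 0, and without PBS replicate 1 it was 0.46. Leaving out PBS replicate 3 also brought NDRG1 to 0.32, ADM to 0.097, VEGFA to 0.16 and SLC2A1 to 0.21, while ANGPTL4 had 0.51.

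**Figure D1:**
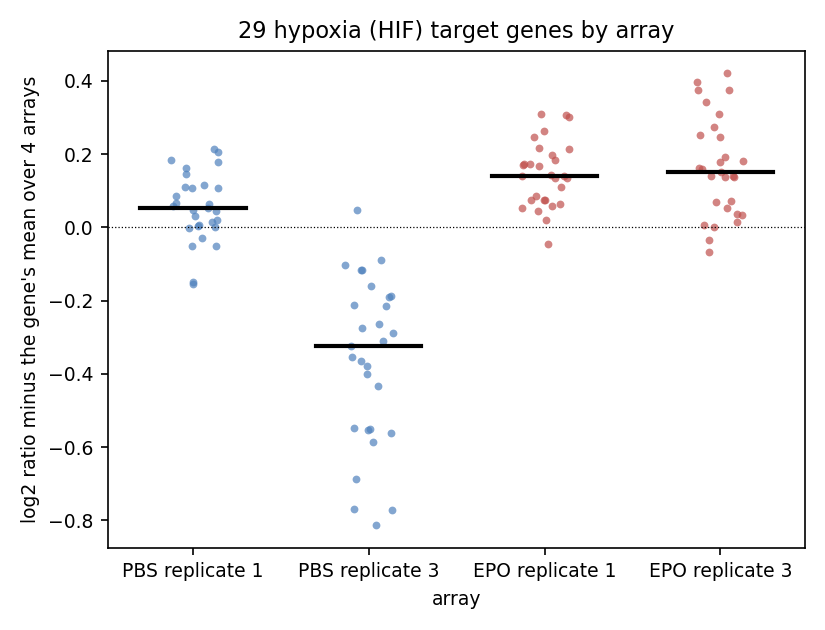
Log2 ratio of each of 29 hypoxia target genes minus the gene's mean over the 4 arrays (y axis) on each array (x axis). Points are genes, blue for PBS and red for EPO, and bars are medians. PBS replicate 3 was the lowest array for 28 of 29 genes.

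Glycolysis enzymes, some of which are also hypoxia targets, had a median of 0.10 over 18 genes (camera adjusted p = 0.045, and 0.866 with an estimated correlation), with 17 of 18 above 0. HK2, which catalyses the entry step, had 0.50 ± 0.24 and ENO2 0.46 ± 0.30, while PKM had 0.01 ± 0.11 and LDHB -0.11 ± 0.07. No member passed over all genes, 0 passed adjusted over the list alone and 1 had an unadjusted p under 0.05. Here too PBS replicate 3 was lowest of the 4 arrays in 15 of 18 genes, and without it the median turned to -0.03 (adjusted p = 0.997) and HK2 and ENO2 fell to 0.18 and 0.058. The call also ended without EPO replicate 3 (median 0.10, adjusted p = 0.381). After quantile normalization (0.11, adjusted p = 0.066), after centring each array (0.11, 0.057) and at 1 SD per array (0.11, 0.052) the median was as large and p lay just past the threshold. At 1 median absolute deviation per array the call held (0.11, 0.032).

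Epithelial junction genes lay higher with EPO as a list, with 25 of 29 above 0. The median was 0.13 over 29 genes (camera adjusted p = 4.59e-05, and 0.866 with an estimated correlation). PKP1, a desmosomal plaque protein, had the largest difference, 0.99 ± 0.09, a fold of 1.99 (PBS arrays 2.23 and 2.20, EPO arrays 3.29 and 3.13). The desmosomal cadherin DSG3 had 0.58 ± 0.12. ESRP1, an epithelial splicing regulator, had -0.03 ± 0.10 and the tight junction gene CLDN1 -0.19 ± 0.09 (0.16 with 1 feature per gene). Of the 29 genes 5 had an unadjusted p under 0.05, all higher, and 1 passed adjusted over the list alone (PKP1, adjusted p = 0.015), against 0 over all genes. Quantile normalization brought the median to 0.07 and the adjusted p to 0.136, and the difference of DSG3 to 0.088, while PKP1 had 0.83. At 1 median absolute deviation per array the median was also 0.07, with the call held (0.021). At 1 SD per array it was 0.041 and the call ended (camera adjusted p = 0.078).

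Basal breast genes also lay higher with EPO as a list, with 15 of 19 above 0. The median was 0.17 over 19 genes (camera adjusted p = 0.0054, and 0.866 with an estimated correlation). S100A2 had 0.54 ± 0.08, the laminin gene LAMB3 0.51 ± 0.09 and the basal keratin gene KRT5 0.42 ± 0.10, whereas CRYAB, a small heat shock protein, had -0.85 ± 0.15 and VGLL1 -0.25 ± 0.18. At an unadjusted p under 0.05, 7 members were higher and 1 lower. S100A2, LAMB3 and CRYAB were the 3 that passed adjusted over the list alone (adjusted p = 0.037 each), with 0 over all genes. The list's call ended without PBS replicate 3 (median 0.04, adjusted p = 0.527), without EPO replicate 3 (median 0.16, adjusted p = 0.165) and after quantile normalization (median 0.12, adjusted p = 0.196). That normalization brought S100A2 to 0.12, LAMB3 to 0.24 and KRT5 to 0.18, and CRYAB to -0.76.

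Inflammatory genes under NF-kappaB lay higher with EPO as a list, with 25 of 29 above 0. The median was 0.17 over 29 genes (camera adjusted p = 1.28e-04, and 0.866 with an estimated correlation). The granulocyte growth factor gene CSF3 had 0.54 ± 0.15, IL1A 0.54 ± 0.12 and IL1B 0.45 ± 0.14. CCL2 had -0.17 ± 0.09 and the collagenase gene MMP1 -0.18 ± 0.10, and after quantile normalization these were 0.17 and 0.07. The same normalization brought CSF3 to 0.19, IL1A to 0.20, IL1B to 0.074 and the list's median to 0.12. CSF3 had 0.35 without EPO replicate 3. With an unadjusted p under 0.05 there were 4 members, all higher, 0 passed adjusted over the list alone and 0 over all genes. For this list the call held in each of the normalizations tried and without any 1 array.

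**Figure D2:**
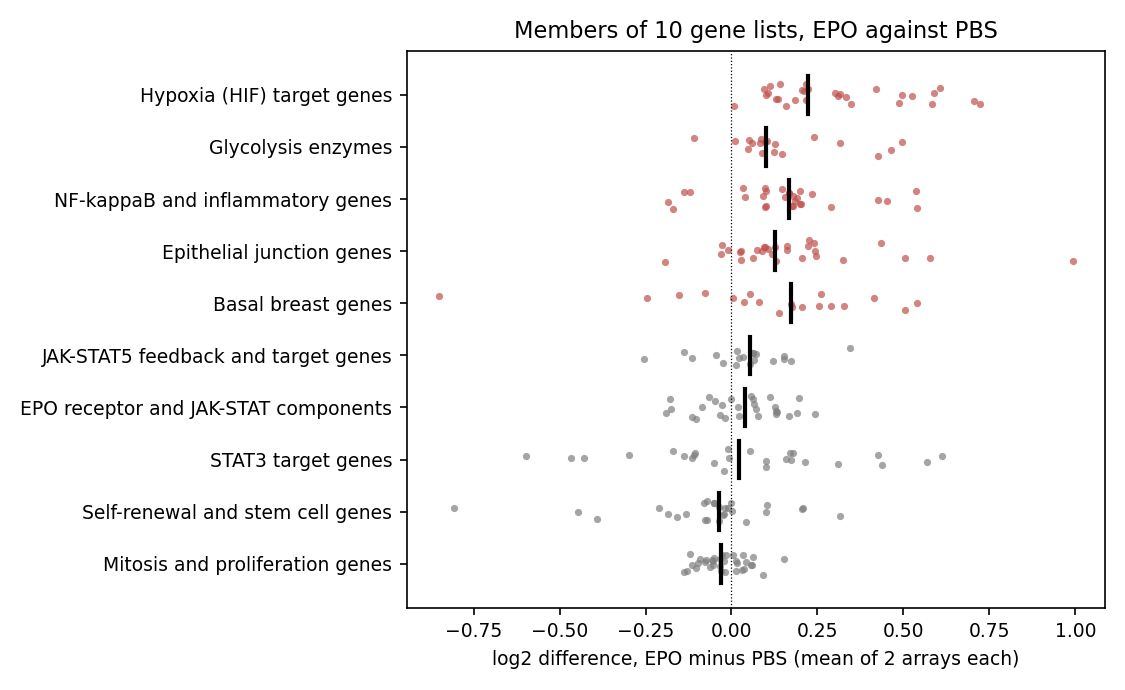
Log2 difference, EPO minus PBS, of each member (points, x axis) of 10 gene lists (y axis), with the list's median as a bar. The 5 lists in red passed camera with its preset correlation, with medians from 0.10 to 0.22, and those in grey did not.

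Genes far from the reference level lay slightly further from it on the EPO arrays, which the called lists share in part. The 53 genes with a mean ratio above 4 had a median difference of 0.36 and the 233 genes below -4 one of -0.18. Across genes, the slope of the difference on the mean ratio was 0.060, against 0.020 and 0.028 in the other splits of the arrays. A gradient also lay between the PBS arrays. Replicate 1 minus replicate 3 had a median of 0.25 below -4 and -0.10 above 4. For the EPO arrays these were 0.06 and -0.035. Epithelial junction genes had a median ratio to the reference of 1.43, basal genes 0.96, inflammatory genes 0.71, hypoxia genes 0.15 and glycolysis genes -0.15.

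**Figure D3:**
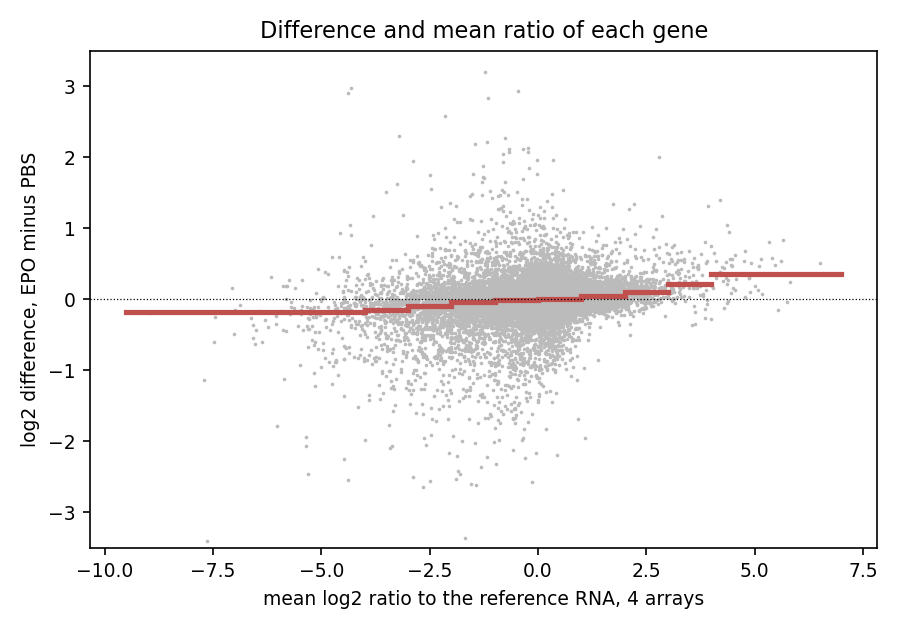
Log2 difference, EPO minus PBS (y axis), against the mean log2 ratio to the reference over 4 arrays (x axis) for each gene, with 7 genes outside the y axis. Red lines are medians within ranges of the mean ratio, from -0.18 below -4 to 0.36 above 4.

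No gene or list of EPO's own receptor pathway was called at the RNA level, and pathway activity itself was not measured. EPOR, the receptor gene, had a difference of -0.03 (95% confidence interval -0.32 to 0.26), JAK2 -0.17 (-0.39 to 0.04), STAT5A -0.06 (-0.37 to 0.24), STAT5B -0.10 (-0.31 to 0.10) and STAT3 -0.02 (-0.23 to 0.19). EPO itself had 0.13 (-0.29 to 0.55). Among the feedback and target genes of JAK-STAT5 signalling, SOCS1, a feedback inhibitor, had the largest difference, 0.34 (0.05 to 0.64; limma adjusted p = 0.524). Other named members were CISH at -0.14 (-0.37 to 0.10), SOCS2 at 0.02 (-0.23 to 0.27), SOCS3 at 0.17 (-0.16 to 0.51), PIM1 at 0.06 (-0.24 to 0.37), BCL2L1 at -0.11 (-0.32 to 0.09) and IGF1 at -0.25 (-0.84 to 0.33). The intervals printed here exclude a change of 1 on the log2 scale, while that of IL2RA, another member, named after its values were seen, does not (-0.89 to 1.20). The signs of STAT3 and STAT5A turned after quantile normalization (0.013 and 0.081) and that of IGF1 with 1 feature per gene (0.29), and those of EPOR, EPO, SOCS2, PIM1, STAT4 and PRLR turned when 1 array was left out. As groups, the 19 JAK-STAT5 genes had a median of 0.06 (camera adjusted p = 0.546; 98.6 percentile of matched random lists, and 90.2 without PBS replicate 3), the 28 receptor and JAK-STAT components one of 0.04 (0.589) and the 26 STAT3 target genes one of 0.02 (0.546). Among components, PRLR had 0.24 ± 0.26, IL6R 0.20 ± 0.13, STAT4 -0.18 ± 0.23 and LIFR -0.19 ± 0.12. The STAT3 target MMP9, a gelatinase gene, had 0.57 ± 0.08 and FOS 0.61 ± 0.34, while FGA had -0.47 ± 0.31 and A2M -0.60 ± 0.12. LCN2 of this list had 0.44 ± 0.10. After quantile normalization MMP9 had 0.15, A2M -0.16, FGA -0.19, LCN2 0.056 and LIFR -0.018. LIFR had -0.058 without PBS replicate 1, and without EPO replicate 3 FGA had -0.057 and FOS 0.24, so these differences depend on single arrays.

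Self-renewal genes were not called as a group either. Their median difference was -0.04 over 27 genes (camera adjusted p = 0.546), with 7 of 27 above 0. Fry gave an unadjusted p of 0.050 and an adjusted p of 0.343. BMI1, a polycomb gene of stem cell maintenance, had -0.02 (95% confidence interval -0.22 to 0.18), MYC -0.05 (-0.41 to 0.31) and CD44 0.10 (-0.10 to 0.31). The sorting-gate genes CD24 and EPCAM, outside this list, had 0.32 (-0.38 to 1.02) and -0.03 (-0.55 to 0.49). SOX9 had 0.31 ± 0.11 and KLF5 0.21 ± 0.10, whereas PROM1, which encodes the stem cell marker CD133, had -0.81 ± 0.24 and LGR5 -0.45 ± 0.24. Without EPO replicate 3 PROM1 shrank to -0.51 and LGR5 to -0.26, and without PBS replicate 1 LGR5 shrank to -0.18. The signs of BMI1, MYC and EPCAM turned when 1 array was left out. No member passed over all genes or adjusted over the list alone (0), with 1 higher and 2 lower at an unadjusted p under 0.05. Developmental pathways gave medians of 0.07 for 25 Notch genes (camera adjusted p = 0.546), -0.02 for 36 Wnt genes (0.643), 0.06 for 12 hedgehog genes (0.862) and 0.05 for 26 TGF-beta genes (0.457). The Notch ligand JAG2 had -0.39 ± 0.13, the Wnt feedback gene AXIN2 -0.57 ± 0.13 and the ligand WNT10B 0.43 ± 0.12.

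Proliferation lists were not called. The 34 mitosis genes had a median of -0.03 (camera adjusted p = 0.546; 3.01 percentile of matched random lists, and 1.43 without PBS replicate 3, where the median was -0.01) and ran from AURKB at 0.15 ± 0.12 to CCNB1 at -0.14 ± 0.10, with MKI67 at 0.09 ± 0.15. Medians were -0.05 for 34 DNA replication genes (0.546), 0.04 for 18 histone genes (0.546), where H2AC6 had -0.69 ± 0.16, 0.05 for 22 PI3K-AKT-FOXO genes (0.402) and 0.06 for 28 MAPK and immediate early genes (0.386). Luminal breast genes had a median of 0.02 over 23 genes (0.628) and mesenchymal genes one of -0.01 over 29 (0.864). Among the latter, the stromelysin gene MMP3 had -0.95 ± 0.15, at a mean ratio of -5.01 to the reference. The 37 interferon-stimulated genes had -0.04 (0.589), with the antiviral gene OAS2 at -1.35 ± 0.29.

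Metabolic and stress lists also stayed short of the threshold. The 20 cholesterol synthesis genes had a median of 0.02 (camera adjusted p = 0.268), with MSMO1 at 0.39 ± 0.09 (0.19 after quantile normalization). The 20 metallothionein and oxidative stress genes had 0.06 (0.308), with HMOX1 at 0.36 ± 0.10. Oxidative phosphorylation gave -0.0045 over 48 genes (0.874), cytosolic ribosomal proteins -0.02 over 51 (0.652), the unfolded protein response 0.02 over 25 (0.546), where DNAJC3 had -0.60 ± 0.13 (but 0.18 with 1 feature per gene), and ATF4 stress genes 0.0045 over 24 (0.955). Heat shock genes had -0.02 over 20 (0.746), p53 targets 0.03 over 26 (0.519) and apoptosis regulators 0.0037 over 32 (0.740). Fry gave the p53 targets an unadjusted p of 0.0023, the lowest of the lists, and an adjusted p of 0.077. Over the 29 lists without a call the lowest adjusted p was 0.268. Without PBS replicate 3 the medians of 8 of these 29 lists changed sign, among them DNA replication (0.025), interferon-stimulated (0.019) and cytosolic ribosomal protein genes (0.023). Leaving out another array turned 3 to 6 of them, so the signs of these medians are not read as a response.

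Markers of other cells were set beside these. Erythroid genes, the classic targets of the hormone, had a median of -0.04 over 25 genes (camera adjusted p = 0.864). HBM, a globin gene of the alpha cluster, had 1.34 ± 0.09 and was the 1 member that passed adjusted over the list alone (adjusted p = 0.0045), against 0.254 over all genes. HBQ1, of the same cluster, went the other way with -0.36 ± 0.08. SLC4A1, the red cell anion exchanger, had a larger but uncertain difference of 1.51 ± 0.93, which fell to 0.28 without PBS replicate 1 and to 0.10 with 1 feature per gene. Fibroblast genes had a median of -0.21 over 12 genes (0.308), which shrank to -0.097 without PBS replicate 3, and endothelial genes -0.02 over 12 (0.546). Immune genes had -0.04 over 18 (0.546), yet 6 of them passed adjusted over the list alone, and these went both ways: CSF1R with 0.74 ± 0.16, MS4A1 with 0.69 ± 0.07 and CD2 with 0.61 ± 0.10, and JCHAIN with -1.13 ± 0.11 (-0.68 with 1 feature per gene), PTPRC with -0.35 ± 0.08 and ITGAM with -0.34 ± 0.08. None of the 6 passed over all genes, and JCHAIN had a mean ratio of -5.87 to the reference. Median, mean and test differed in sign for 4 lists: hedgehog (mean -0.01, test up), mesenchymal (mean -0.03, test up), erythroid (mean 0.06, test down) and immune genes (mean 0.0085, test down).

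In all, 5 of 34 lists passed camera with its preset correlation, all higher with EPO. With an estimated correlation 0 passed. That form of camera rests on 2 residual degrees of freedom here, so it could hardly have called a list among 34. The estimated correlation was -0.03 for epithelial junction, 0.12 for basal, 0.11 for inflammatory, 0.71 for hypoxia and 0.58 for glycolysis genes. Its adjusted p of 0.866 thus does not by itself show that correlation among genes explains the calls. With fry, which asks whether a list's genes move one way, 0 passed (lowest adjusted p 0.077, for epithelial junction genes and p53 targets). Camera on ranks called 5. Against random lists matched on mean ratio, some lists without a call also stood high, with Notch genes at the 99.4 percentile, MAPK genes at 98.7 and JAK-STAT5 genes at 98.6, and DNA replication genes stood low, at the 2.22 percentile. Without PBS replicate 3 these were 93.8, 89.6, 90.2 and 69.5, while mitosis genes moved further out. With 2 arrays per group, no exact permutation p can fall below 0.333. Whether the arrays stand for separate cultures is not stated in the labels.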

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

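Scaling each array to 1 SD or to 1 median absolute deviation, and the count at an unadjusted p under 0.05, were tests chosen after the data were seen. No gene passed limma's threshold under any alternative that kept all 4 arrays. Leaving out 1 array gave 0 to 2 genes, with LINC00317 and TAFA1 called without EPO replicate 3 (adjusted p = 0.042 for both), both named after their values were seen; in each, EPO replicate 1 was far below the other 3 arrays. The lone array is then assumed to vary like the other group. Genes at an unadjusted p under 0.05 numbered 2476 for single features, 920 without the genes nearest the reference level (fewer were tested), and 1229 to 2538 with 1 array left out. Genes apart by at least 1 numbered 591 for single features, 1124 at a minimum of 0.5, and 439 to 508 with 1 array left out, since fewer arrays then have to lie apart. Called lists numbered 2 after quantile normalization and 2 at 1 SD (hypoxia and NF-kappaB in both), 4 at 1 median absolute deviation (all but basal genes), 0 with an estimated correlation, 0 with fry, and 3 to 8 with 1 array left out; the cause was not tested. The liver and melanocyte genes had a median ratio of -4.18 with the brightest-ratio feature of each gene, which picks higher ratios by construction.

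Samples with the same replicate number showed no shared deviation: the deviations of PBS and EPO arrays correlated at -0.0018. This does not settle whether they were paired by design. With the replicate number as a block, 0 genes passed, 1512 had an unadjusted p under 0.05 and 5 lists passed. Of 950 values of 95 named genes under 10 alternatives, 913 kept their direction and 37 in 20 genes reversed. Part of the 913 could not reverse. The replicate block leaves each difference as it is, and a gene with no overlap between groups cannot turn when 1 array is left out. The differences that reversed had passed no test, but 0 genes passed over all genes in any case. Among the 95, quantile normalization made 22 differences smaller and 9 larger by over 1.5 times, and scaling to 1 SD 23 and 9; genes far from the reference level are those that scaling moves most by construction. Leaving out PBS replicate 3 made 17 smaller and 7 larger and turned 9, leaving out PBS replicate 1 made 5 smaller and 20 larger and turned 4, and leaving out an EPO array made 4 to 12 smaller. Without PBS replicate 3 CD24 shrank to 0.054, SOX9 to 0.21, FOS to 0.35, SOCS3 to 0.076, IL6R to 0.056 and VGLL1 to -0.060. Without EPO replicate 3 CD24 shrank to 0.14 and SOCS3 to 0.084, and without EPO replicate 1 CISH shrank to -0.074 and VGLL1 to -0.11. After quantile normalization JAK2 shrank to -0.11, STAT5B to -0.018, CISH to -0.092, CD44 to 0.044 and JAG2 to -0.25. Of 60 values of the called lists, 38 kept their call, 21 lost it and 1 reversed.

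After quantile normalization, at 1 SD and at 1 median absolute deviation, in this order, STAT3 was 0.013, 0.020 and 0.0087, STAT5A 0.081, 0.073 and 0.028, and CCL2 0.17, 0.14 and 0.043. MMP1 was 0.071 after quantile normalization and 0.036 at 1 SD. With 1 feature per gene MYC was 0.05, CLDN1 0.16, MMP1 0.023, PKM -0.028, IGF1 0.29 and DNAJC3 0.18; the cause was not tested. Leaving out 1 array at a time gave these ranges for results that reversed in at least 1 case: EPOR -0.13 to 0.068, STAT5A -0.18 to 0.049, SOCS2 -0.052 to 0.086, IGF1 -0.52 to 0.010, Glycolysis enzymes -0.032 to 0.24, PIM1 -0.044 to 0.17, MYC -0.16 to 0.057, BMI1 -0.053 to 0.013, EPCAM -0.26 to 0.20, ESRP1 -0.12 to 0.062, KDM3A -0.11 to 0.12, PKM -0.098 to 0.12, STAT4 -0.48 to 0.12, MKI67 -0.097 to 0.28, EPO -0.0020 to 0.26, STAT3 -0.062 to 0.025 and PRLR -0.071 to 0.56; with 1 array fewer in a group, that group's value rests on its other array. The alternative chosen for features with missing values was not run, since no value was missing. Signal over background, which sets how far ratios of dim features can be trusted, was not analysed here.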

Other observations

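Quantile normalization, leaving out each array and the other splits of the arrays were chosen before the data were seen, and the bound for the epidermal differentiation list before its result was seen. The tests against matched random lists, the binomial interval and the use of all these against single explanations were chosen after the results they bear on were seen. For the spread of log ratios, the rule that the percentile and the call or median after scaling must point one way was set after these values were seen, as was the weight given to the gap between the PBS arrays.

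The high differences of CASP14 and PKP1 raised the hypothesis that genes of epidermal differentiation are higher with EPO as a group. A list of 69 such genes was written, without these 2, and 62 were measured. Single members, named after their values were seen, went both ways. SERPINB4, a protease inhibitor, had a log2 difference of 0.68 ± 0.16 (SE), the skin lipoxygenase genes ALOXE3 and ALOX12B 0.67 ± 0.20 and 0.61 ± 0.07, the elastase inhibitor gene PI3 0.44 ± 0.09 and the mucosal keratin gene KRT13 0.41 ± 0.09. The skin proteases KLK5 and KLK7 had -0.92 ± 0.15 and -0.70 ± 0.49, and the cornified layer genes RPTN and FLG -0.58 ± 0.22 and -0.09 ± 0.20. The list's median of 0.03 lay at the 76.0 percentile of matched random lists, short of the bound, so the hypothesis in this form was not borne out. At an unadjusted p under 0.05, 8 members were higher and 1 lower, and the set tests, unadjusted, gave p = 0.022 with camera, p = 0.10 with an estimated correlation and p = 0.0021 with fry.

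The 5 called lists could reflect the wider spread of log ratios on the EPO arrays, which lifts genes above the reference level, rather than a response of their genes. By SD both EPO arrays were widest, but by median absolute deviation PBS replicate 3 (1.05) was as wide as EPO replicates 1 and 3 (1.06 and 1.05) and PBS replicate 1 alone was narrow (0.98). Against random lists matched on mean ratio, the median lay at the 95.6 percentile for epithelial junction genes. Their call ended after quantile normalization (median 0.13, quartiles 0.064 to 0.24, before, and 0.07, -0.043 to 0.18, after). It also ended at 1 SD per array (0.041, camera adjusted p = 0.078) but held at 1 median absolute deviation per array (0.07, adjusted p = 0.021). Spread may thus account for part of that median and stays open as the whole cause. For hypoxia genes the percentile was 100 and for inflammatory genes 99.97, and both calls of camera with its preset correlation held after quantile normalization, which argues against spread as the whole cause of these medians, though CSF3, IL1A and IL1B shrank with it. Glycolysis genes lay at the 99.8 percentile, and their call ended after quantile normalization although the median did not shrink (0.10, quartiles 0.065 to 0.22, before, and 0.11, 0.071 to 0.27, after), since p lay close to the threshold on either side (0.045 and 0.066). With a median ratio of -0.15 to the reference, this argues against spread as the whole cause there too, if the median is accepted in place of the call. That choice was made after these values were seen. Where the call itself has to hold, spread stays open for glycolysis genes. Basal genes (99.3) lost their call with a smaller median (0.17, quartiles 0.021 to 0.27, before, and 0.12, 0.048 to 0.17, after), so spread stays open for them. A response to the hormone was not tested apart from these.

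For hypoxia, glycolysis and basal genes, a low PBS replicate 3 is a candidate explanation of the higher medians. Without that array the glycolysis list fell to the 26.4 percentile of matched lists and the basal list to 30.9, in line with that explanation, although S100A2, LAMB3 and KRT5 still differed by 0.49, 0.53 and 0.47. The hypoxia list lay at the 99.4 percentile without it, with a median of 0.10, but its genes vary together far more than those of random lists. The median left is smaller than the gap of 0.40 between the PBS arrays and rests on PBS replicate 1 alone. Whether EPO shifted hypoxia genes or samples differed in this programme for other reasons stays open.

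More genes were lower than higher among the 291 apart by at least 1 (210 of them, 72.2%). Noise of dim features that is alike on all arrays would give as many falls in another split, and the highest number there was 85. Each other split sets 1 PBS and 1 EPO array on either side. Noise larger on both EPO arrays would add genes to each split, but could add more falls to the real split, so it stays open. Wider spread on the EPO arrays would be removed by quantile normalization, after which 67.1% were still falls (exact binomial 95% interval 60.9 to 72.8%, with genes taken as independent). A loss of dim transcripts with EPO and a batch shared by the EPO arrays stay open as hypotheses, and neither could be tested with ratios alone.

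The 1530 genes at an unadjusted p under 0.05 were set against the other splits of the 4 arrays. The real split was the 1 of 3 with as many, and the highest other gave 600, below the 917 given by chance alone. The splits are not separate comparisons: a gene with 4 distinct values is apart in exactly 1 of them. A surplus in 1 split thus lowers the others and widens the contrast. With 3 splits no share under 0.05 can be reached.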
